A study of Arabidopsis thaliana with 16 samples.

How the data were processed

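Poly(A) RNA (RNA-seq) and ribosome-protected RNA fragments (Ribo-seq) came from 10-day-old Arabidopsis seedlings of the wild type Col-0 and the fust1 mutant, kept at 22 °C or treated at 37 °C. Per the labels, RNA was selected with oligo-dT, and footprints were made with RNase I, passed over sizing columns and depleted of ribosomal RNA. The duration of the heat was not given in the sources used here. Each of the 8 groups had 2 libraries.

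The deposited values were whole-number read counts per gene, without normalization, for 27628 genes (27420 nuclear, 88 plastid and 120 mitochondrial, 0 of ribosomal RNA). The submitters' processing notes name fastp 0.19.7, STAR 2.7.3a, featureCounts 1.6.2 and Bowtie 1.0.1 with the TAIR10 genome. The role of each tool per assay, a length filter for footprints and the counted feature (coding sequence or exon) were not given in the sources used here. Symbols came from a name table of a later release, used for names only: 10361 genes had a symbol, and 208 organelle genes were not in it. The gene that gives the mutant its name was not in the table under that name and is not reported.

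Genes passed edgeR's filterByExpr (minimum count 10, by group) within each assay, 19340 for RNA and 18445 for footprints, and 17816 passed both for TE. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, robust) in R 4.3.3, with 4 residual degrees of freedom per assay and 8 for TE. TE was the interaction of assay with the comparison over all 16 libraries. The 15 comparisons were heat in Col-0, heat in fust1, genotype (fust1 minus Col-0) at 22 °C and at 37 °C, and heat by genotype (heat in fust1 minus heat in Col-0), each for RNA, footprints and TE. Adjusted p-values are Benjamini-Hochberg values, with calls at 0.05. Standard errors are the absolute log2 change over the square root of F, and log CPM used a prior count of 2. A fold against a group without counts used a floor of 3 counts over the group.

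The 16 gene lists (304 genes) were heat shock factors, small heat shock proteins, cytosolic and organelle chaperones, ER unfolded protein response, cytosolic ribosomal proteins, translation factors, stress granule and mRNA decay proteins, nuclear photosynthesis genes, ABA, drought and cold genes, oxidative stress genes, warm growth and auxin genes, circadian clock genes, defence genes, cell division and histone genes, root markers, and shoot epidermis and stomata markers. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Named genes were, per comparison, up to 5 with the largest called rise and up to 5 with the largest called fall among those with at least 10 CPM in the higher group and no overlap between libraries, up to 4 members per list with the smallest adjusted p, the top 10 of heat by genotype, and HSP101, HSFA2, HSP21, HSP70 (HSP70-4), HSP90.1, MBF1C, APX2, DREB2A and BIP3. Groups, comparisons, tests, lists, this rule and the alternatives were chosen before the data were examined, except the thinned libraries and the minimum of 500 footprints, which were added later.

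The procedure was tested on simulated data with 100 changed genes per fold. Of genes changed 4-fold, 81.0 % were recovered for RNA genotype at 37 °C, 52.0 % for RNA heat by genotype, 78.0 % and 70.0 % for the same comparisons of footprints, and 44.0 % and 7.00 % for TE, so TE heat by genotype misses most changes of that size. Of genes changed 2-fold, 18.0 %, 2.0 %, 49.0 %, 29.0 %, 4.00 % and 1.0 % were recovered. Unchanged genes made up 6.60 to 16.7 % of calls, above the nominal 5 %. A simulated ratio of heat responses of 1 was recovered as 0.994, 0.982 and 0.973 (RNA, footprints, TE), and 0.7 as 0.709, 0.713 and 0.721. A list raised 1.5-fold was recovered by camera (adjusted p = 5.09e-27), with 0 other lists called. The simulated genes were drawn independently of each other, so this does not test for false list calls among correlated genes.

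Alternatives were DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, nuclear genes only, a term for replicate number, only the groups compared, and each library left out in turn. Footprint libraries were also thinned with seed 20240611, to 6175906 counts each or to the smallest effective size (total times TMM factor), and the ratio of heat responses was also taken over genes with at least 100 counts or 500 footprints and without the heat lists. Footprint length, reading frame, codon positions, transcript features and the uniqueness of reads between gene copies were not analysed here, because the deposit held gene counts without positions. Ribosomal RNA could not be left out of the totals, as 0 such genes were in the table.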

Results

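RNA-seq measured how much RNA each gene had, and Ribo-seq counted the stretches of RNA that ribosomes covered (footprints), in 10-day-old Arabidopsis seedlings. The wild type Col-0 and the fust1 mutant were kept at 22 °C or exposed to 37 °C, with n = 2 libraries for every genotype, temperature and assay, so 16 libraries in 8 groups. RNA-seq libraries held 9762754 and 12737375 counts (Col-0, 22 °C) and 11673902 and 10274343 (Col-0, 37 °C). In fust1 they held 9752875 and 9402134 (22 °C) and 9752318 and 11170562 (37 °C). Ribo-seq libraries held 13732127 and 10831678 counts (Col-0, 22 °C) and 6271023 and 6175906 (Col-0, 37 °C). In fust1 they held 13870246 and 13968790 (22 °C) and 9785425 and 11927823 (37 °C). In the shallow Col-0 37 °C footprint group 865 of 18445 tested genes had no count, against 269 in fust1 at 37 °C. The labels do not say whether replicates were separate cultures, so the p-values measure spread between these samples. Floors for groups without a count cover counting error only, because PCR copies were counted as reads without molecular identifiers. No added standard was counted, so each value is relative to the rest of its library and the total amount of translation was not measured.

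Heat gave a few chaperone genes a large part of each library. The heat shock factor, small heat shock protein and chaperone lists (50 genes) took 20.1 ± 2.31 % of RNA counts in Col-0 at 37 °C and 19.1 ± 2.63 % in fust1 (mean ± SD, n = 2), from 0.356 ± 0.0395 % and 0.449 ± 0.0325 % at 22 °C. Of the footprints they took 46.3 ± 1.80 % in Col-0 and 45.0 ± 0.554 % in fust1, from 0.577 ± 0.0391 % and 0.771 ± 0.00267 %. Plastid-encoded genes went the other way by share, from 5.12 ± 0.338 % to 1.4 ± 0.140 % of footprints in Col-0 and from 5.25 ± 1.48 % to 0.867 ± 0.111 % in fust1. These are shares of library totals, while the CPM and log2 changes below are on the TMM scale. Footprint TMM factors were 1.76 and 1.79 (Col-0) and 1.81 and 1.96 (fust1) at 22 °C. At 37 °C they were 0.489 and 0.532 (Col-0) and 0.563 and 0.614 (fust1). A gene with an unchanged footprint share thus rises on the TMM scale, so the plastid fall by share is not a fall of that size there. The shares were not tested; an exact permutation test of 2 against 2 libraries cannot give p under 0.333.

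**Figure D1:**
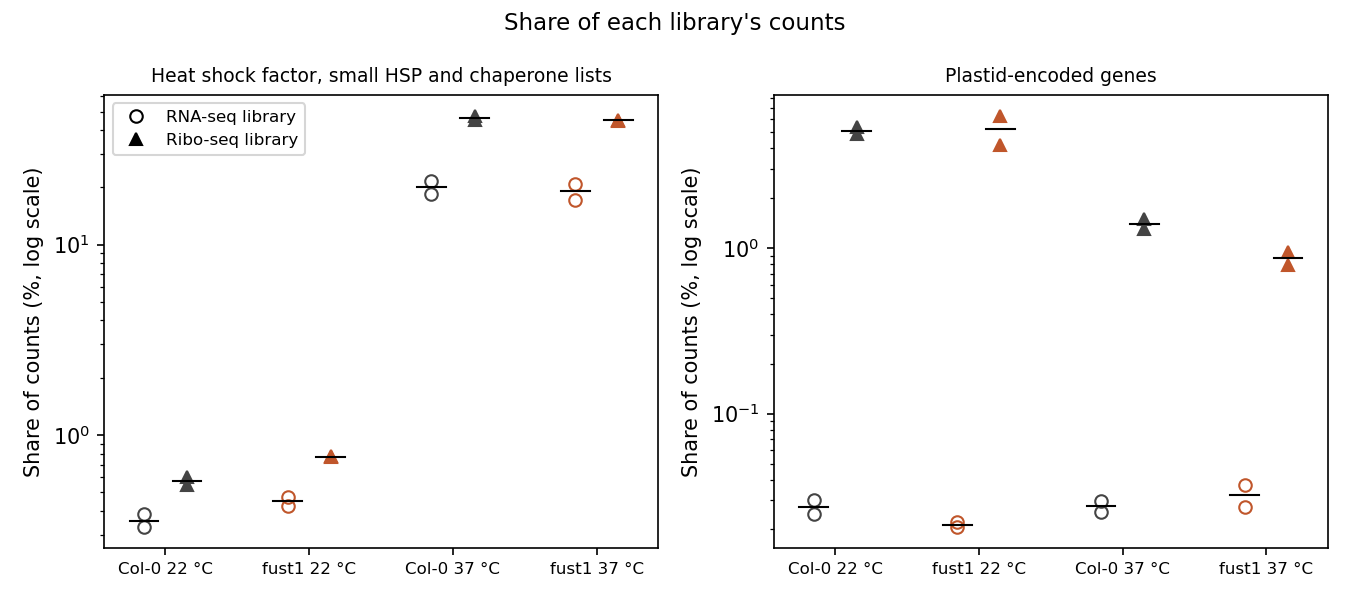
Share of each library's counts, in percent on a log scale, on the heat shock factor, small heat shock protein and chaperone lists (left) and on plastid-encoded genes (right). Open circles are RNA-seq libraries, filled triangles are Ribo-seq libraries, lines mark the mean of 2, grey is Col-0 and orange is fust1.

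Heat in Col-0 asked which RNAs a wild-type seedling gains and loses at 37 °C. Some chaperone genes came on from almost nothing. HSP101, the disaggregase needed to survive heat, went from 7.02 ± 0.808 to 26584 ± 633 CPM (counts scaled to equal TMM-adjusted library sizes, not to library totals). Its log2 change was 11.89 ± 0.41, adjusted p = 9.74e-09. Other members of the chaperone list, such as AT3G09440 at 143 ± 22.1 CPM, already had much RNA at 22 °C. HSFA2, the factor that sustains the response, rose by 13.75 ± 0.44 on the log2 scale, MBF1C by 10.21 ± 0.36 and DREB2A by 7.30 ± 0.34. HSP70 rose by 10.78 ± 0.54, HSP90.1 by 11.54 ± 0.56 and the plastid protein HSP21 by 13.90 ± 0.64. AT1G53540, ATHSP22.0 and APX2 had no count at 22 °C and rose at least 98854-fold, 72169-fold and 5376-fold. The ER chaperone BIP3 was not called (-2.50 ± 1.75, adjusted p = 0.280). Among the losses were SPL9, a factor for the change from juvenile to adult leaves, from 11.5 ± 3.41 CPM to no count (at least 56.9-fold). MYB34, which drives indole glucosinolate synthesis, fell as well (-6.49 ± 0.67, adjusted p = 5.81e-05). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3705 genes higher and 3511 lower of 19340, of which 2113 and 2939 at least 2-fold.

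In the RNA of Col-0 at 37 °C, heat shock factors had 11 of 13 higher and 0 lower (11 and 1 adjusted over the list alone), median 5.98, adjusted p = 1.54e-38 (adjusted p = 0.00124 with an estimated correlation). The small heat shock proteins had 14 of 15 higher and 0 lower (14 and 0 adjusted over the list alone), median 14.04 (13.90 without members at zero in a group), adjusted p = 6.89e-131 (adjusted p = 0.00124 with an estimated correlation). The chaperone list had 21 of 22 higher and 0 lower (21 and 0 adjusted over the list alone), median 6.91, adjusted p = 4.40e-86 (adjusted p = 0.00275 with an estimated correlation). The ER unfolded protein response list, led by BIP1 (3.53 ± 0.24), had 9 of 13 higher and 0 lower (9 and 0 adjusted over the list alone), median 1.31, adjusted p = 8.62e-07 (adjusted p = 0.224 with an estimated correlation). Oxidative stress genes had 9 of 13 higher and 1 lower (9 and 2 adjusted over the list alone), median 1.49 (1.37 without members at zero in a group), adjusted p = 6.92e-08 (adjusted p = 0.0452 with an estimated correlation). Nuclear photosynthesis genes had 21 of 39 higher and 0 lower (24 and 1 adjusted over the list alone), median 0.84, adjusted p = 0.000459 (adjusted p = 0.744 with an estimated correlation). Their share of RNA totals did not rise, at 20.2 ± 1.11 % (22 °C) and 16.6 ± 3.65 % (37 °C). Cell division and histone genes, led by the histone H4 gene AT3G45930 (-3.13 ± 0.32), had 0 of 20 higher and 14 lower (0 and 14 adjusted over the list alone), median -2.0, adjusted p = 5.84e-08 (adjusted p = 0.224 with an estimated correlation). Root markers had 0 of 15 higher and 5 lower (0 and 4 adjusted over the list alone), median -2.27 (-1.97 with zero-count members at their bound, -2.09 without members at zero in a group), adjusted p = 0.0379 (adjusted p = 0.744 with an estimated correlation).

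Other lists gave no call for RNA in Col-0. Cytosolic ribosomal proteins had 1 of 33 higher and 1 lower (0 and 1 adjusted over the list alone), median 0.17, adjusted p = 0.770. Translation factors had 9 of 28 higher and 2 lower (9 and 2 adjusted over the list alone), median 0.36, adjusted p = 0.15. Stress granule and mRNA decay proteins, with DCP5 at -1.38 ± 0.19, had 3 of 18 higher and 4 lower (3 and 4 adjusted over the list alone), median 0.16, mean -0.00436, test direction down, adjusted p = 0.966. ABA, drought and cold genes, with COR47 at 2.88 ± 0.25, had 7 of 19 higher and 1 lower (7 and 1 adjusted over the list alone), median 0.24, adjusted p = 0.15. Warm growth and auxin genes had 3 of 16 higher and 2 lower (3 and 1 adjusted over the list alone), median -0.30, adjusted p = 0.872. Circadian clock genes, with PRR5 at -3.05 ± 0.37, had 5 of 12 higher and 4 lower (5 and 4 adjusted over the list alone), median 0.57, adjusted p = 0.770. Defence genes, with SARD1 at 5.68 ± 0.48, had 5 of 12 higher and 1 lower (6 and 1 adjusted over the list alone), median 0.89, adjusted p = 0.0600. Shoot epidermis and stomata markers had 0 of 10 higher and 2 lower (0 and 1 adjusted over the list alone), median -0.20 (-0.11 without members at zero in a group), adjusted p = 0.430. Without the Col-0 22 °C RNA-seq replicate 1 the count of called genes was 3497, and without replicate 2 it was 3988.

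Footprints in Col-0 asked what the ribosomes of a heated wild-type seedling hold. HSP101 footprints rose from 10.8 ± 6.12 to 98338 ± 12584 CPM (13.13 ± 0.39, adjusted p = 1.10e-16). HSP70 footprints reached 129051 ± 10729 CPM at 37 °C (10.92 ± 0.28, adjusted p = 5.10e-23). HSP21 rose by 13.93 ± 0.35, HSFA2 by 12.31 ± 0.42 and HSP90.1 by 11.77 ± 0.28. MBF1C rose by 11.06 ± 0.23, DREB2A by 9.41 ± 0.23 and Hsp70b by 13.61 ± 1.12 on the log2 scale. Among translation factors, eIFiso4G1 fell (-4.58 ± 0.25, adjusted p = 2.24e-15). So did the eIF5B gene AT1G76810 (-4.25 ± 0.29), EIF3C (-2.69 ± 0.17) and the stress granule protein Tudor1 (-3.44 ± 0.20). The Calvin cycle gene GAPA fell (-3.31 ± 0.16). The cold gene COR47 and the defence factor WRKY70 rose (3.59 ± 0.16 and 5.44 ± 0.18). Footprints of emb2458 (38.1 ± 5.55 CPM at 22 °C), FIP1[V], IRX1 and the photoperiod gene FKF1 reached zero. They lost at least 80.6-fold, 45.8-fold, 39.8-fold and 38.8-fold. The test called 5135 genes higher and 5871 lower of 18445, of which 3715 and 5054 at least 2-fold.

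For Col-0 footprints, heat shock factors had 11 of 12 higher and 0 lower (11 and 0 adjusted over the list alone), median 6.83, adjusted p = 2.51e-32 (adjusted p = 0.00306 with an estimated correlation). Small heat shock proteins had 15 of 15 higher and 0 lower (15 and 0 adjusted over the list alone), median 13.13, adjusted p = 1.15e-42 (adjusted p = 0.0325 with an estimated correlation). Chaperones had 19 of 22 higher and 1 lower (19 and 1 adjusted over the list alone), median 6.65, adjusted p = 4.26e-53 (adjusted p = 0.00306 with an estimated correlation). The ER list had 8 of 13 higher and 1 lower (8 and 1 adjusted over the list alone), median 1.24, adjusted p = 4.41e-05 (adjusted p = 0.0962 with an estimated correlation). Oxidative stress genes had 10 of 13 higher and 2 lower (10 and 2 adjusted over the list alone), median 1.33, adjusted p = 1.86e-13 (adjusted p = 0.00906 with an estimated correlation). ABA, drought and cold genes had 12 of 19 higher and 2 lower (12 and 2 adjusted over the list alone), median 1.14, adjusted p = 0.00194 (adjusted p = 0.331 with an estimated correlation). The nuclear photosynthesis list had 24 of 39 higher and 12 lower (24 and 12 adjusted over the list alone), median 0.88, adjusted p = 0.0222 (adjusted p = 0.692 with an estimated correlation). Its share of footprint totals fell from 12.2 ± 0.733 % to 6.27 ± 0.0709 %, so the positive median is relative to the typical gene on the TMM scale. Translation factors had 9 of 28 higher and 11 lower (10 and 11 adjusted over the list alone), median -0.12, adjusted p = 0.184. Stress granule and mRNA decay proteins had 6 of 17 higher and 8 lower (6 and 8 adjusted over the list alone), median -0.62, adjusted p = 0.185. Between Col-0 RNA and footprints, 2042 genes were higher in both (1002 expected from the margins) and 2039 lower in both (1076). Another 620 were higher in RNA and lower in footprints (1145 expected) and 138 the reverse (941).

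Translation efficiency (TE, the footprint change beyond the RNA change) asked which genes gained or lost footprints relative to their poly(A) RNA in Col-0 at 37 °C. Only the RNA libraries were selected with oligo-dT, so a change in RNA without a poly(A) tail was not measured and TE need not be translation per copy. Each assay was also scaled on its own, so TE is relative to the typical gene. CAF1a, a deadenylase subunit, kept its footprints (12.4 ± 3.42 and 12.2 ± 2.61 CPM) while its RNA went from 27.6 ± 3.84 to 0.781 ± 0.424 CPM. Its TE rose by 5.17 ± 0.52, adjusted p = 9.23e-07. The resistance gene HSPRO2 rose by 4.30 ± 0.32, adjusted p = 3.42e-08, and DREB2A by 2.12 ± 0.36, adjusted p = 0.000227. The secondary wall gene CESA4 had more RNA (7.56 ± 1.03 to 69.6 ± 14.2 CPM) and fewer footprints. Its TE change was -8.00 ± 0.55, adjusted p = 2.36e-08. AT1G76810 changed by -5.01 ± 0.33, adjusted p = 1.70e-08 and GAPA by -4.31 ± 0.33. HSP70 was not called (0.14 ± 0.45, adjusted p = 0.838). Translation factors had 5 of 28 higher and 14 lower (6 and 14 adjusted over the list alone), median -0.64, adjusted p = 0.0101 (adjusted p = 0.591 with an estimated correlation). Cell division and histone genes had 12 of 20 higher and 0 lower (14 and 0 adjusted over the list alone), median 1.36, adjusted p = 0.000150 (adjusted p = 0.591 with an estimated correlation). Heat shock factors had 4 of 12 higher and 1 lower (5 and 2 adjusted over the list alone), median 0.35, adjusted p = 0.340. The small heat shock proteins had 2 of 15 higher and 3 lower (2 and 4 adjusted over the list alone), median -0.96 (0.03 without members at zero in a group), adjusted p = 0.874. Chaperones had 3 of 22 higher and 8 lower (4 and 9 adjusted over the list alone), median -0.38, adjusted p = 0.129. The test called 2761 genes higher and 3832 lower of 17816, of which 2269 and 3577 at least 2-fold. The TE calls of HSP101 (1.25 ± 0.44, adjusted p = 0.0324) and MBF1C (0.85 ± 0.31, adjusted p = 0.0405) ended when most single libraries were left out.

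Heat in fust1 asked whether the mutant mounts the same RNA response. Its core genes came on: HSP101 rose from 11.1 ± 0.274 to 20297 ± 3471 CPM (10.84 ± 0.40, adjusted p = 1.59e-08). HSFA2 rose by 10.63 ± 0.38, HSP70 by 9.19 ± 0.51 and HSP90.1 by 10.25 ± 0.53. MBF1C rose by 9.03 ± 0.34, DREB2A by 6.09 ± 0.32 and HSP21 by 13.16 ± 0.61. ATHSP22.0 and APX2 rose from no count at least 70359-fold and 5698-fold. CAF1a fell from 42.6 ± 7.04 to 0.383 ± 0.192 CPM (-6.77 ± 0.41, adjusted p = 3.40e-07). The test called 3635 genes higher and 3471 lower of 19340 (2101 and 2818 at least 2-fold). Of these, 2616 were higher in both genotypes (696 expected), 2245 lower in both (630) and 14 plus 2 opposite. Heat shock factors had 11 of 13 higher and 1 lower (11 and 1 adjusted over the list alone), median 5.27, adjusted p = 3.26e-35 (adjusted p = 0.00149 with an estimated correlation). Small heat shock proteins had 14 of 15 higher and 0 lower (14 and 0 adjusted over the list alone), median 12.82 (12.68 without members at zero in a group), adjusted p = 4.59e-134 (adjusted p = 0.00149 with an estimated correlation). Chaperones had 21 of 22 higher and 0 lower (22 and 0 adjusted over the list alone), median 6.09, adjusted p = 1.21e-80 (adjusted p = 0.00680 with an estimated correlation). The ER list had 8 of 13 higher and 0 lower (8 and 0 adjusted over the list alone), median 1.43, adjusted p = 4.79e-07 (adjusted p = 0.237 with an estimated correlation). Ribosomal proteins, led by SAG24 (1.18 ± 0.22), had 23 of 33 higher and 0 lower (28 and 0 adjusted over the list alone), median 0.96, adjusted p = 2.86e-05 (adjusted p = 0.620 with an estimated correlation). Without the fust1 22 °C RNA-seq replicate 1 the count of called genes was 4685, and without the fust1 37 °C replicate 2 it was 4185.

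In the RNA of heated fust1, cell division and histone genes had 1 of 20 higher and 11 lower (1 and 12 adjusted over the list alone), median -1.33, adjusted p = 0.000629 (adjusted p = 0.495 with an estimated correlation). Oxidative stress genes had 6 of 13 higher and 2 lower (6 and 2 adjusted over the list alone), median 0.49 (0.48 without members at zero in a group), adjusted p = 0.000367 (adjusted p = 0.155 with an estimated correlation). Nuclear photosynthesis genes had 10 of 39 higher and 0 lower (9 and 0 adjusted over the list alone), median 0.69, adjusted p = 0.0103 (adjusted p = 0.851 with an estimated correlation). Translation factors had 12 of 28 higher and 3 lower (14 and 3 adjusted over the list alone), median 0.42, adjusted p = 0.0417 (adjusted p = 0.620 with an estimated correlation). Defence genes, with FRK1 at -4.17 ± 0.44, had 1 of 12 higher and 2 lower (1 and 1 adjusted over the list alone), median -0.23, adjusted p = 0.671.

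Footprints in fust1 asked the same of its ribosomes. HSP101 rose by 12.01 ± 0.37, adjusted p = 2.64e-16, HSP70 by 10.35 ± 0.27 and HSP21 by 12.80 ± 0.33. HSP90.1 rose by 11.16 ± 0.28, MBF1C by 10.27 ± 0.23, DREB2A by 8.81 ± 0.23 and APX2 by 11.64 ± 0.26. AT5G53680, without a count at 22 °C, rose at least 1055-fold. The initiation factors eIFiso4G1 (-2.87 ± 0.19, adjusted p = 1.54e-13), AT1G76810 (-2.56 ± 0.21) and EIF3C (-2.09 ± 0.16) fell. So did GAPA (-1.83 ± 0.15) and SLP2 (-6.02 ± 0.38, adjusted p = 3.70e-12). The test called 5082 genes higher and 5761 lower of 18445 (3171 and 4594 at least 2-fold). Of these, 4086 were higher in both genotypes (1415 expected), 4427 lower in both (1834) and 41 plus 46 opposite. Between RNA and footprints of fust1, 2067 genes were higher in both (974 expected) and 2185 lower in both (1046). Another 377 were higher in RNA and lower in footprints (1096) and 175 the reverse (930).

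For fust1 footprints, heat shock factors had 10 of 12 higher and 0 lower (10 and 0 adjusted over the list alone), median 7.11, adjusted p = 1.40e-34 (adjusted p = 0.00175 with an estimated correlation). The small heat shock proteins had 15 of 15 higher and 0 lower (15 and 0 adjusted over the list alone), median 12.19, adjusted p = 2.62e-42 (adjusted p = 0.0489 with an estimated correlation). Chaperones had 20 of 22 higher and 1 lower (20 and 1 adjusted over the list alone), median 6.07, adjusted p = 8.58e-56 (adjusted p = 0.00166 with an estimated correlation). The ER list had 9 of 13 higher and 1 lower (9 and 1 adjusted over the list alone), median 0.96, adjusted p = 3.30e-05 (adjusted p = 0.0887 with an estimated correlation). Oxidative stress genes had 10 of 13 higher and 3 lower (10 and 3 adjusted over the list alone), median 1.64, adjusted p = 6.54e-13 (adjusted p = 0.0103 with an estimated correlation). ABA, drought and cold genes had 10 of 19 higher and 1 lower (10 and 1 adjusted over the list alone), median 1.09, adjusted p = 0.0113 (adjusted p = 0.410 with an estimated correlation). The nuclear photosynthesis list had 25 of 39 higher and 6 lower (25 and 6 adjusted over the list alone), median 0.70, adjusted p = 0.00730 (adjusted p = 0.611 with an estimated correlation). Here too its share of footprint totals fell, from 10.7 ± 0.853 % to 5.78 ± 0.395 %. The cell division and histone list had 2 of 20 higher and 15 lower (3 and 16 adjusted over the list alone), median -1.30, adjusted p = 0.000603 (adjusted p = 0.378 with an estimated correlation). Ribosomal proteins had 8 of 33 higher and 7 lower (8 and 7 adjusted over the list alone), median 0.02, mean -0.03, test direction down, adjusted p = 0.814.

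For TE in fust1 the question was which genes gained or lost footprints relative to their poly(A) RNA in heat, with the same limits. HSPRO2 rose by 4.43 ± 0.31, adjusted p = 1.11e-07, AT4G29780 by 4.42 ± 0.34 and CAF1a by 4.47 ± 0.59, adjusted p = 3.43e-05. DREB2A rose by 2.72 ± 0.36, adjusted p = 3.30e-05 and MBF1C by 1.23 ± 0.30, adjusted p = 0.00529. The plastid genes ATCG00680 and ATCG00070 had values of -6.49 ± 0.61 and -6.13 ± 0.41, but oligo-dT selection holds little plastid RNA, so these do not measure translation per copy. The ribosomal protein gene RPS5B changed by -2.25 ± 0.29, adjusted p = 2.59e-05. Ribosomal proteins had 0 of 33 higher and 15 lower (0 and 20 adjusted over the list alone), median -0.86, adjusted p = 1.50e-05 (adjusted p = 0.591 with an estimated correlation). Translation factors had 0 of 28 higher and 15 lower (0 and 15 adjusted over the list alone), median -0.78, adjusted p = 1.50e-05 (adjusted p = 0.166 with an estimated correlation). Heat shock factors had 5 of 12 higher and 0 lower (6 and 0 adjusted over the list alone), median 1.21, adjusted p = 0.00554 (adjusted p = 0.166 with an estimated correlation). ABA, drought and cold genes had 9 of 19 higher and 1 lower (9 and 1 adjusted over the list alone), median 1.62 (1.5 without members at zero in a group), adjusted p = 0.00155 (adjusted p = 0.505 with an estimated correlation). Oxidative stress genes had 7 of 13 higher and 1 lower (7 and 1 adjusted over the list alone), median 0.78 (0.94 without members at zero in a group), adjusted p = 0.00251 (adjusted p = 0.166 with an estimated correlation). Warm growth genes had 5 of 15 higher and 0 lower (5 and 0 adjusted over the list alone), median 0.72 (0.65 without members at zero in a group), adjusted p = 0.0446 (adjusted p = 0.334 with an estimated correlation). Defence genes had 4 of 12 higher and 0 lower (4 and 0 adjusted over the list alone), median 0.36, adjusted p = 0.0391 (adjusted p = 0.505 with an estimated correlation). The test called 2233 genes higher and 2805 lower of 17816 (1863 and 2504 at least 2-fold). Of these, 1238 were higher in both genotypes (346 expected), 2196 lower in both (603) and 4 plus 6 opposite. The TE call of RAB18 (4.31 ± 1.41, adjusted p = 0.0480) ended when most single libraries were left out.

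Genotype at 22 °C asked what fust1 changes before any heat. SQN, a cyclophilin needed for microRNA activity, had 80 and 100 RNA counts in Col-0 and 0 and 0 in fust1 (adjusted p = 0.000464). The defence factor WRKY33 stood higher in fust1, at 117 ± 3.52 against 27.9 ± 3.29 CPM (2.06 ± 0.26, adjusted p = 0.0232). SZF1 (1.80 ± 0.24, adjusted p = 0.0309) and the ethylene factor ERF2 (2.50 ± 0.35, adjusted p = 0.0353) were higher too. So were the resistance gene AT5G41750 (2.58 ± 0.29, adjusted p = 0.0118), AT4G12490 (2.58 ± 0.28, adjusted p = 0.0118) and HSFA2 (2.87 ± 0.37, adjusted p = 0.0232). LCBK2, a sphingoid base kinase, was lower (-1.77 ± 0.26, adjusted p = 0.0474). Defence genes had 0 of 12 higher and 0 lower (5 and 0 adjusted over the list alone), median 1.14, adjusted p = 5.24e-11 (adjusted p = 0.129 with an estimated correlation), and the median was 0.299 without the fust1 22 °C RNA-seq replicate 1. Heat shock factors had 1 of 13 higher and 0 lower (3 and 0 adjusted over the list alone), median 0.28, adjusted p = 2.52e-06 (adjusted p = 0.0991 with an estimated correlation). Small heat shock proteins had 0 of 15 higher and 0 lower (2 and 0 adjusted over the list alone), median 0.82 (0.14 with zero-count members at their bound), adjusted p = 0.000544 (adjusted p = 0.238 with an estimated correlation). Chaperones had 0 of 22 higher and 0 lower (0 and 0 adjusted over the list alone), median 0.35, adjusted p = 1.91e-10 (adjusted p = 0.171 with an estimated correlation). Root markers had 0 of 15 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.91, adjusted p = 2.31e-06 (adjusted p = 0.269 with an estimated correlation). Nuclear photosynthesis genes had 0 of 39 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.21, adjusted p = 2.69e-05 (adjusted p = 0.647 with an estimated correlation). The test called 9 genes higher and 2 lower of 19340, with 672 at unadjusted p < 0.05. The count moved between 1 (without the Col-0 22 °C RNA-seq replicate 1) and 67 (without the Col-0 37 °C replicate 2), and was 83 with DESeq2. The calls of WRKY33, SZF1, ERF2, HSFA2, AT5G41750 and LCBK2 ended without either Col-0 22 °C RNA-seq library or without the fust1 22 °C replicate 1.

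In footprints at 22 °C WRKY33 was not called (0.12 ± 0.22, adjusted p = 0.838). The calmodulin-binding factor AT5G64220 was higher in fust1 (24.5 ± 1.91 against 6.09 ± 0.0595 CPM; 2.01 ± 0.19, adjusted p = 1.51e-07). Higher too were STZ (1.52 ± 0.17, adjusted p = 3.20e-06), CYP712A1 (1.88 ± 0.21, adjusted p = 3.20e-06), the cold gene COR15A (1.25 ± 0.24, adjusted p = 0.00302) and the receptor kinase FRK1 (1.22 ± 0.23, adjusted p = 0.00176). AT5G11330 was lower (-3.96 ± 0.23, adjusted p = 3.39e-12). Lower too were MRN1 (-2.12 ± 0.26, adjusted p = 1.44e-05), the expansin EXPA8 (-1.24 ± 0.17, adjusted p = 0.000135) and the antenna gene LHCA4 (-0.97 ± 0.16, adjusted p = 0.000608). SQN, picked after its value was seen as it was for RNA, had 176 and 138 footprint counts in Col-0 and 0 and 1 in fust1 (adjusted p = 3.16e-09). Ribosomal proteins, with RPS6 at 0.77 ± 0.14, had 18 of 33 higher and 0 lower (29 and 0 adjusted over the list alone), median 0.50, adjusted p = 1.01e-23 (adjusted p = 0.171 with an estimated correlation). Cell division and histone genes had 8 of 20 higher and 0 lower (13 and 0 adjusted over the list alone), median 0.58, adjusted p = 1.71e-12 (adjusted p = 0.175 with an estimated correlation). Chaperones had 0 of 22 higher and 0 lower (7 and 0 adjusted over the list alone), median 0.36, adjusted p = 4.06e-06 (adjusted p = 0.122 with an estimated correlation). The small heat shock proteins had 1 of 15 higher and 0 lower (2 and 0 adjusted over the list alone), median 0.69, adjusted p = 1.08e-06 (adjusted p = 0.352 with an estimated correlation). The nuclear photosynthesis list had 0 of 39 higher and 8 lower (2 and 13 adjusted over the list alone), median -0.19, adjusted p = 4.41e-05 (adjusted p = 0.528 with an estimated correlation). The test called 426 genes higher and 382 lower of 18445 (98 and 70 at least 2-fold). The count fell to 141 and 357 without the Col-0 22 °C Ribo-seq replicate 1 or 2 and to 244 and 206 without the fust1 22 °C replicate 1 or 2. It was 1371 and 1361 without the fust1 37 °C replicate 1 or 2.

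For TE at 22 °C, only AT5G11330 was called of 17816 genes (0 higher, 1 lower; -2.92 ± 0.33, adjusted p = 0.00135), with 866 at unadjusted p < 0.05 and 18 called by DESeq2. Ribosomal proteins had 0 of 33 higher and 0 lower (0 and 0 adjusted over the list alone), median 0.57, adjusted p = 6.78e-17 (adjusted p = 0.274 with an estimated correlation). Defence genes had 0 of 12 higher and 0 lower (0 and 2 adjusted over the list alone), median -0.71, adjusted p = 1.67e-05 (adjusted p = 0.227 with an estimated correlation). The cell division and histone list had 0 of 20 higher and 0 lower (0 and 0 adjusted over the list alone), median 0.44, adjusted p = 1.38e-05 (adjusted p = 0.274 with an estimated correlation). Heat shock factors had 0 of 12 higher and 0 lower (0 and 1 adjusted over the list alone), median -0.37, adjusted p = 0.0231 (adjusted p = 0.227 with an estimated correlation). Root markers had 0 of 13 higher and 0 lower (0 and 0 adjusted over the list alone), median 0.69, adjusted p = 3.66e-05 (adjusted p = 0.274 with an estimated correlation). The AT5G11330 call ended without the fust1 22 °C Ribo-seq replicate 2 (0 called), and the count was 3, 3 and 10 without the Col-0 37 °C RNA-seq replicate 1, its replicate 2 or the fust1 22 °C RNA-seq replicate 2.

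Genotype at 37 °C asked how the heated mutant differs from the heated wild type. In RNA, SQN had 60.7 ± 1.24 CPM in Col-0 and 0.318 ± 0.10 in fust1 (-7.53 ± 0.36, adjusted p = 1.62e-05). AT4G12490 was higher in fust1 (2.12 ± 0.28, adjusted p = 0.0355), as was the nuclear matrix gene LINC3 (1.61 ± 0.23, adjusted p = 0.0427). The sulfur deficiency gene LSU1 was lower (-2.11 ± 0.30, adjusted p = 0.0367). Lower too were EXPA8 (-1.91 ± 0.24, adjusted p = 0.0355), AT5G11330 (-1.89 ± 0.25, adjusted p = 0.0355) and the methionine sulfoxide reductase MSRB6 (-1.85 ± 0.26, adjusted p = 0.0367). HSP101 was not called (-0.39 ± 0.26, adjusted p = 0.521). Ribosomal proteins had 0 of 33 higher and 0 lower (29 and 0 adjusted over the list alone), median 0.70, adjusted p = 1.88e-18 (adjusted p = 0.550 with an estimated correlation), and the median was 0.44 without the Col-0 37 °C RNA-seq replicate 2 and 1.02 without replicate 1. Cell division and histone genes had 0 of 20 higher and 0 lower (6 and 0 adjusted over the list alone), median 0.93, adjusted p = 9.67e-11 (adjusted p = 0.461 with an estimated correlation). Warm growth and auxin genes had 0 of 16 higher and 1 lower (1 and 7 adjusted over the list alone), median -1.17 (-0.91 with zero-count members at their bound, -0.91 without members at zero in a group), adjusted p = 1.47e-07 (adjusted p = 0.145 with an estimated correlation). Nuclear photosynthesis genes had 0 of 39 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.34, adjusted p = 1.47e-07 (adjusted p = 0.550 with an estimated correlation). Chaperones had 0 of 22 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.27, adjusted p = 0.0343 (adjusted p = 0.550 with an estimated correlation). Defence genes had 0 of 12 higher and 0 lower (0 and 2 adjusted over the list alone), median -0.64, adjusted p = 0.00910 (adjusted p = 0.550 with an estimated correlation). The test called 3 genes higher and 7 lower of 19340, with 2821 at unadjusted p < 0.05 and 305 called by DESeq2. The 2 Col-0 37 °C RNA-seq replicates differed most among RNA-seq groups. Their chi-square per degree of freedom was 29.0, against 7.57 (Col-0, 22 °C), 19.0 (fust1, 22 °C) and 20.0 (fust1, 37 °C). The few RNA calls beside many footprint calls thus do not show that RNA differs less. The count was 1 without either Col-0 22 °C or either fust1 37 °C RNA-seq library, which left only SQN, and 1678 without the Col-0 37 °C RNA-seq replicate 1.

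In footprints at 37 °C fust1 held ribosomes on some RNAs that Col-0 had nearly emptied. The bromodomain gene GTE2 stood at 19.3 ± 2.87 CPM against 0.805 ± 0.708 (4.61 ± 0.49, adjusted p = 7.70e-07). The RNA helicase gene DRH1 stood at 10.5 ± 0.559 against 1.26 ± 0.0627 (3.05 ± 0.42, adjusted p = 2.47e-05). AT4G33720 (3.54 ± 0.44, adjusted p = 8.06e-06), CYP712A1 (2.67 ± 0.27, adjusted p = 3.31e-07), eIFiso4G1 (1.53 ± 0.30, adjusted p = 0.00143), EIF3E (1.34 ± 0.22, adjusted p = 0.000167) and the plastid chaperone CR88 (1.12 ± 0.14, adjusted p = 1.11e-05) were higher too. SQN (-4.10 ± 0.48, adjusted p = 3.73e-06), AT5G11330 (-4.06 ± 0.28, adjusted p = 1.91e-10), AT1G14250 (-2.67 ± 0.25, adjusted p = 6.81e-08) and WRKY70 (-1.02 ± 0.15, adjusted p = 5.97e-05) were lower. Calls within a list went both ways. The translation factor eIFiso4G2 (-0.657 ± 0.16, adjusted p = 0.00821) and the chaperone Hsp70-2 (-0.601 ± 0.135, adjusted p = 0.00437) were lower. The defence gene EDS16 was lower (-0.719 ± 0.187, adjusted p = 0.0128). CBP60G (1.867 ± 0.501, adjusted p = 0.0155) and PR1 (3.997 ± 1.065, adjusted p = 0.0157), also defence genes, were higher. These 2 rest on few counts: over both Col-0 37 °C libraries CBP60G had 9 footprints and PR1 had 2. In RNA at 37 °C CBP60G had the other sign (-1.33 ± 0.36) and was not called. HSP101 (-0.34 ± 0.24, adjusted p = 0.389) and HSP70 (-0.32 ± 0.18, adjusted p = 0.275) were not called. Ribosomal proteins had 7 of 33 higher and 0 lower (12 and 0 adjusted over the list alone), median 0.26, adjusted p = 0.00886 (adjusted p = 0.643 with an estimated correlation). The nuclear photosynthesis list had 3 of 39 higher and 11 lower (5 and 19 adjusted over the list alone), median -0.36, adjusted p = 0.00649 (adjusted p = 0.643 with an estimated correlation). Warm growth and auxin genes had 1 of 15 higher and 2 lower (1 and 2 adjusted over the list alone), median -0.78 (-0.81 without members at zero in a group), adjusted p = 0.0133 (adjusted p = 0.643 with an estimated correlation). The cell division and histone list had 1 of 20 higher and 2 lower (1 and 5 adjusted over the list alone), median -0.38, adjusted p = 0.0255 (adjusted p = 0.643 with an estimated correlation). Stress granule and mRNA decay proteins had 7 of 17 higher and 0 lower (8 and 1 adjusted over the list alone), median 0.54, adjusted p = 0.128. The test called 1127 genes higher and 853 lower of 18445 (726 and 287 at least 2-fold). Between 22 °C and 37 °C, 55 genes were higher in fust1 at both (26.0 expected) and 71 lower at both (17.7). Opposite were 28 (19.7 expected) and 65 (23.3). The count was 780 without the Col-0 37 °C Ribo-seq replicate 1 and 1197 without the fust1 37 °C replicate 2, and either omission ended the call of DREB2A (-0.65 ± 0.16, adjusted p = 0.00741).

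For TE at 37 °C the difference was mostly upward in fust1. GTE2 had a TE difference of 4.75 ± 0.49, adjusted p = 0.000303, and the cytochrome P450 reductase gene ATR2 of 2.36 ± 0.31, adjusted p = 0.00330. The cellulose synthase gene CEV1 had 2.39 ± 0.34, adjusted p = 0.00738 and AT2G16940 had 2.52 ± 0.37, adjusted p = 0.00880. Among histone genes, HTB2 (-1.86 ± 0.34, adjusted p = 0.0167), AT5G10400 (-1.93 ± 0.34, adjusted p = 0.0146) and AT1G09200 (-1.69 ± 0.29, adjusted p = 0.0145) were lower. Genes of cell division and histones had 0 of 20 higher and 4 lower (0 and 6 adjusted over the list alone), median -1.30, adjusted p = 2.36e-13 (adjusted p = 0.250 with an estimated correlation). Ribosomal proteins had 0 of 33 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.37, adjusted p = 7.71e-07 (adjusted p = 0.940 with an estimated correlation). The test called 203 genes higher and 32 lower of 17816, and 513 genes with DESeq2. Without the Col-0 37 °C Ribo-seq replicate 1 the count was 15 and the calls of AT2G16940, HTB2, AT5G10400 and AT1G09200 ended. Without the Col-0 37 °C RNA-seq replicate 1 the count was 1276. With only the groups compared in the model, GTE2 alone of these named genes kept its call and 2 genes were called.

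Heat by genotype asked whether the heat change itself differs between fust1 and Col-0. In RNA the called genes all had a lower heat change in the mutant. ERF-1 (-2.91 ± 0.30, adjusted p = 0.0138) went from 13.7 ± 0.622 to 25.4 ± 0.141 CPM in Col-0 and from 47.1 ± 7.46 to 11.6 ± 1.58 in fust1. The others were SHM7 (-2.87 ± 0.35, adjusted p = 0.0391), the jasmonate synthesis gene OPCL1 (-3.19 ± 0.40, adjusted p = 0.0423), WRKY33 (-2.70 ± 0.36, adjusted p = 0.0470), LSU1 (-3.01 ± 0.41, adjusted p = 0.0470) and ERF2 (-3.62 ± 0.50, adjusted p = 0.0470). HSFA2 was just outside the calls (-3.12 ± 0.45, adjusted p = 0.0503). At 37 °C alone WRKY33 (-0.64, adjusted p = 0.285) and HSFA2 (-0.24, adjusted p = 0.685) did not differ by the test, so their lower heat change came mostly from the higher fust1 level at 22 °C. Heat shock factors had 0 of 13 higher and 0 lower (0 and 5 adjusted over the list alone), median -0.63, adjusted p = 3.52e-05 (adjusted p = 0.148 with an estimated correlation). Small heat shock proteins had 0 of 15 higher and 0 lower (0 and 2 adjusted over the list alone), median -0.75, adjusted p = 0.0119 (adjusted p = 0.315 with an estimated correlation). Chaperones had 0 of 22 higher and 0 lower (0 and 0 adjusted over the list alone), median -0.54, adjusted p = 7.76e-08 (adjusted p = 0.220 with an estimated correlation). Defence genes had 0 of 12 higher and 0 lower (0 and 7 adjusted over the list alone), median -1.19, adjusted p = 6.46e-09 (adjusted p = 0.148 with an estimated correlation). Ribosomal proteins had 0 of 33 higher and 0 lower (0 and 0 adjusted over the list alone), median 0.74, adjusted p = 2.98e-14 (adjusted p = 0.315 with an estimated correlation). Cell division and histone genes had 0 of 20 higher and 0 lower (1 and 0 adjusted over the list alone), median 0.90, adjusted p = 3.59e-07 (adjusted p = 0.293 with an estimated correlation). Warm growth and auxin genes had 0 of 16 higher and 0 lower (0 and 1 adjusted over the list alone), median -1.23 (-0.95 without members at zero in a group), adjusted p = 0.000702 (adjusted p = 0.148 with an estimated correlation). ABA, drought and cold genes had 0 of 19 higher and 0 lower (0 and 3 adjusted over the list alone), median -0.69 (-0.63 without members at zero in a group), adjusted p = 0.000153 (adjusted p = 0.354 with an estimated correlation). Oxidative stress genes had 0 of 13 higher and 0 lower (0 and 2 adjusted over the list alone), median -0.54 (-0.59 without members at zero in a group), adjusted p = 0.000153 (adjusted p = 0.148 with an estimated correlation). Root markers had 0 of 15 higher and 0 lower (0 and 0 adjusted over the list alone), median 1.34 (1.33 without members at zero in a group), adjusted p = 0.0119 (adjusted p = 0.522 with an estimated correlation). The test called 0 genes higher and 6 lower of 19340, with 1803 at unadjusted p < 0.05, and DESeq2 called 18 higher and 160 lower. The count was 0 without either Col-0 22 °C RNA-seq library, without the fust1 22 °C replicate 1 or without the fust1 37 °C replicate 2, and 766 without the Col-0 37 °C RNA-seq replicate 1.

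For footprints, some genes fell less in heat in fust1 than in Col-0. HOG1, the S-adenosylhomocysteine hydrolase gene, went from 948 ± 28.9 to 13.5 ± 0.228 CPM in Col-0 and from 1001 ± 54.5 to 60.9 ± 12.6 in fust1 (2.1 ± 0.24, adjusted p = 4.98e-06). SHV3 (2.46 ± 0.25, adjusted p = 1.21e-06), the nitrate reductase NIA2 (2.33 ± 0.24, adjusted p = 1.21e-06) and the plastid GTPase gene SVR3 (3.32 ± 0.37, adjusted p = 2.91e-06) had a higher value in fust1. So did GAPA (1.48 ± 0.21, adjusted p = 4.73e-05). Others had another course: GTE2 (4.94 ± 0.57, adjusted p = 4.54e-06) fell in Col-0 and rose in fust1, the hypoxia gene LBD41 (2.31 ± 0.23, adjusted p = 1.21e-06) rose in both genotypes, and LHCA4 (1.62 ± 0.23, adjusted p = 5.30e-05) fell by 0.80 in Col-0 and rose by 0.82 in fust1 from a lower level. STZ (-2.06 ± 0.23, adjusted p = 2.91e-06), the histone gene AT5G10400 (-1.65 ± 0.26, adjusted p = 0.000190) and MBF1C (-0.79 ± 0.25, adjusted p = 0.0447) had a lower value. HSP101 was not called (-1.13 ± 0.35, adjusted p = 0.0523). The small heat shock proteins had 0 of 15 higher and 1 lower (0 and 1 adjusted over the list alone), median -0.91, adjusted p = 8.46e-05 (adjusted p = 0.502 with an estimated correlation). Chaperones had 2 of 22 higher and 3 lower (3 and 7 adjusted over the list alone), median -0.41, adjusted p = 0.0180 (adjusted p = 0.488 with an estimated correlation). Ribosomal proteins had 1 of 33 higher and 4 lower (1 and 7 adjusted over the list alone), median -0.29, adjusted p = 0.00143 (adjusted p = 0.502 with an estimated correlation). The cell division and histone list had 0 of 20 higher and 7 lower (1 and 12 adjusted over the list alone), median -0.95, adjusted p = 6.30e-08 (adjusted p = 0.488 with an estimated correlation). The test called 1012 genes higher and 593 lower of 18445 (809 and 348 at least 2-fold). The count was 701 without the Col-0 22 °C Ribo-seq replicate 1, 787 without the Col-0 37 °C replicate 1, and 911 and 1048 without the fust1 22 °C replicate 1 or 2. RLE scaling ended the call of MBF1C.

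For TE, 172 genes had a higher and 23 a lower heat change in fust1 of 17816. DRH1 RNA was measured in all 4 groups (181 ± 9.53 to 246 ± 1.96 CPM in Col-0, 181 ± 3.30 to 223 ± 18.3 in fust1). Its footprints went from 17.1 ± 1.11 to 1.26 ± 0.0627 CPM in Col-0 and from 13.4 ± 0.570 to 10.5 ± 0.559 in fust1 (3.53 ± 0.41, adjusted p = 0.00140). GTE2 (4.98 ± 0.60, adjusted p = 0.00140), ATR2 (2.95 ± 0.42, adjusted p = 0.00895) and CEV1 (3.06 ± 0.45, adjusted p = 0.00895) went the same way. So did SVR3 (3.35 ± 0.53, adjusted p = 0.00971), the defence regulator CBP60G (4.65 ± 0.80, adjusted p = 0.0154) and the eIF5B gene AT1G76810 (2.15 ± 0.44, adjusted p = 0.0303). CBP60G had only 9 footprints over both Col-0 37 °C libraries. The histone H4 gene AT3G46320 (-4.72 ± 0.75, adjusted p = 0.00971) and the H3 gene AT1G09200 (-2.06 ± 0.39, adjusted p = 0.0240) went the other way. Ribosomal proteins had 0 of 33 higher and 1 lower (0 and 15 adjusted over the list alone), median -1.03, adjusted p = 3.09e-15 (adjusted p = 0.473 with an estimated correlation). Genes of cell division and histones had 0 of 20 higher and 4 lower (0 and 11 adjusted over the list alone), median -1.91, adjusted p = 1.44e-14 (adjusted p = 0.215 with an estimated correlation). Defence genes had 2 of 12 higher and 0 lower (3 and 0 adjusted over the list alone), median 1.16, adjusted p = 0.00325 (adjusted p = 0.473 with an estimated correlation). DESeq2 called 667 genes. Without the Col-0 37 °C Ribo-seq replicate 1 the count was 23 and the call of SVR3 ended. Without the Col-0 37 °C RNA-seq replicate 1 the count was 1445.

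A ratio set the covariance across genes of the fust1 and Col-0 heat changes over that of independent Col-0 heat changes, where 1 is an equal response and a smaller or a differently ordered fust1 response both lower it. Over 17816 genes it was 0.889 for RNA (0.886 and 0.892 for the 2 ways to pair libraries), 0.796 for footprints (0.795 and 0.796) and 0.672 for TE (0.665 and 0.679). The SD of the heat change across genes, with noise removed, was 1.4 in Col-0 and 1.28 in fust1 for RNA, 1.85 and 1.56 for footprints and 1.43 and 1.08 for TE. The correlation of the 2 genotypes was 0.968, 0.944 and 0.891, so both parts entered the ratio. Set over fust1 in place of Col-0, the ratio was 1.05, 1.12 and 1.18. Genes are not independent replicates, so the ratio has no p-value. Among 3050 genes with at least 500 footprints it was 0.925, 0.846 and 0.706.

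**Figure D2:**
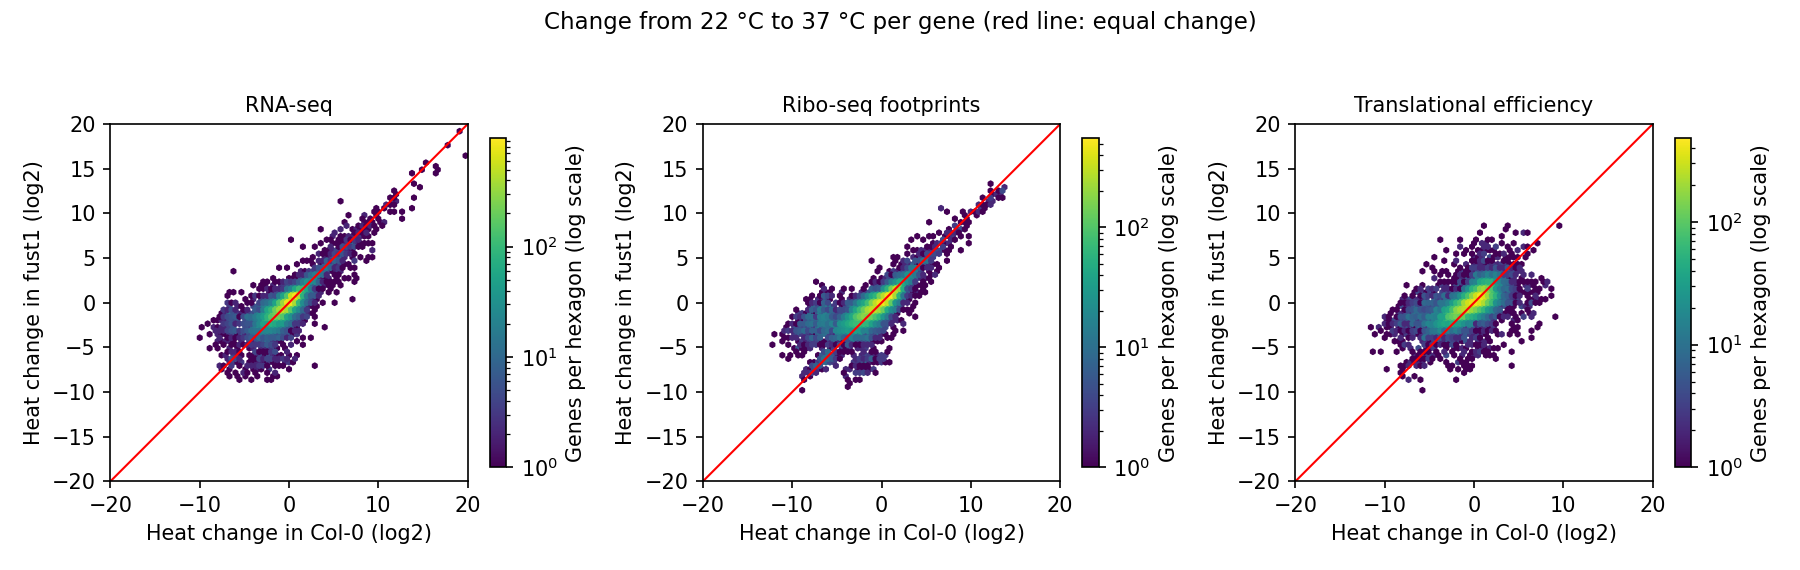
Heat change of each gene in Col-0 (x axis) and fust1 (y axis) on the log2 scale for RNA, footprints and TE, with colour for the number of genes per hexagon on a log scale and a red line at equal change. The clouds at the sides are genes with few or no counts in a group, whose fitted values depend on the prior count.

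**Figure D3:**
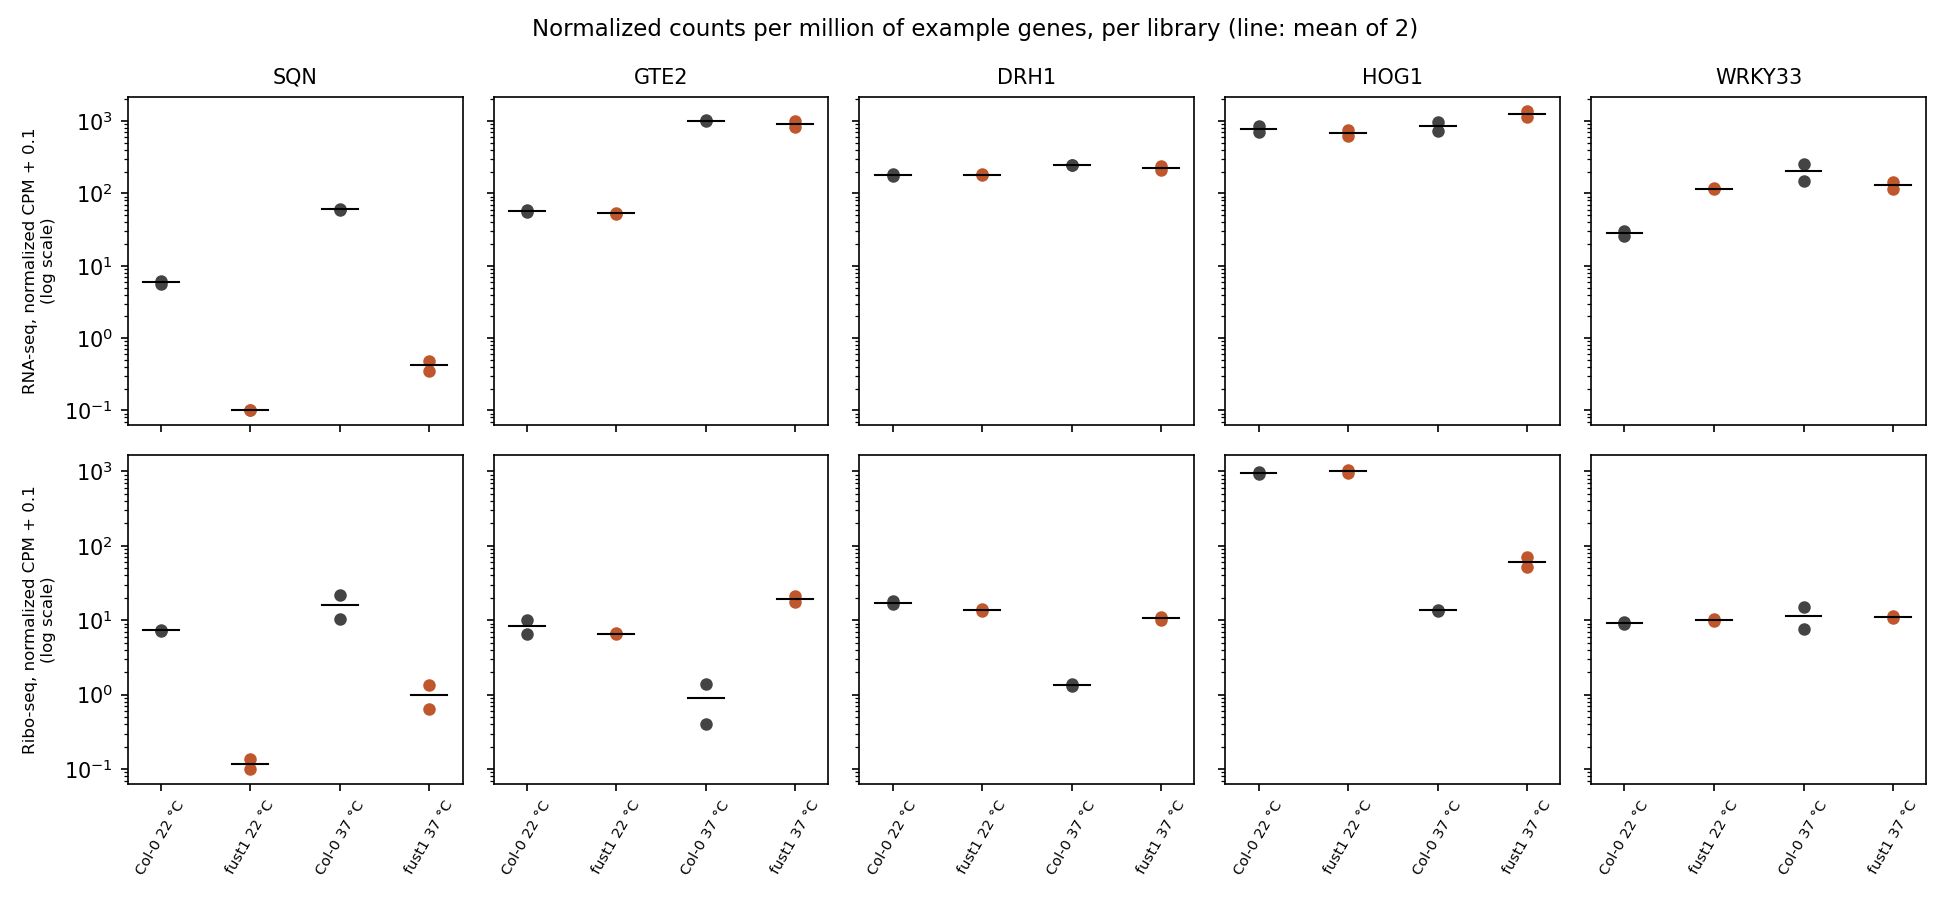
Normalized CPM plus 0.1 on a log axis of SQN, GTE2, DRH1, HOG1 and WRKY33 in RNA-seq (upper panels) and Ribo-seq (lower panels). Points are libraries and lines mark the mean of 2; in heat, footprints of GTE2 and DRH1 fall in Col-0, while in fust1 those of GTE2 rise and the change of DRH1 was not called.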

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

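The tests of single libraries for the defence and ribosomal protein lists, of footprints of the genes called higher at 22 °C, of the deepest footprint falls and of effective depth were chosen after the result was seen, and thinning to equal totals was added then. The test of the difference in heat response between fust1 and Col-0 brought up every value given for RNA, footprints and TE.

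For RNA it called 6 genes: ERF-1 (-2.91), SHM7 (-2.87), OPCL1 (-3.19), WRKY33 (-2.70), LSU1 (-3.01) and ERF2 (-3.62). By list median it brought up heat shock factors (-0.63), small heat shock proteins (-0.75), chaperones (-0.54), ABA, drought and cold genes (-0.69, and -0.63 without members at zero in a group), oxidative stress genes (-0.54, and -0.59 without them), warm growth and auxin genes (-1.23, and -0.95 without them) and defence genes (-1.19). Ribosomal proteins (0.74), cell division and histone genes (0.90) and root markers (1.34, and 1.33 without members at zero) had positive medians. None of these RNA lists kept its call with an estimated correlation.

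For footprints it called 1605 genes, with LBD41 (2.31), SHV3 (2.46), NIA2 (2.33), STZ (-2.06), AT1G74470 (2.50), SVR3 (3.32), AT5G21940 (-1.94), GTE2 (4.94), AT1G19530 (1.83) and HOG1 (2.1) at the top. List medians were -0.91 for small heat shock proteins, -0.41 for chaperones, -0.29 for ribosomal proteins and -0.95 for cell division and histone genes.

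For TE it called 195 genes, with DRH1 (3.53), GTE2 (4.98), ATR2 (2.95), CEV1 (3.06), AT2G26190 (2.74), SVR3 (3.35), AT1G07480 (3.02), ADR1-L2 (2.44) and the histone H4 gene AT3G46320 (-4.72) at the top. AT1G13640 (8.67) had no footprint in Col-0 at 37 °C, so its fitted value depends on the prior count. List medians were -1.03 for ribosomal proteins, 1.16 for defence genes and -1.91 for cell division and histone genes. No list of footprints or TE kept its call with an estimated correlation either.

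The smaller translational response of fust1 could come from carry-over of 22 °C footprints or from the shallow Col-0 37 °C footprint libraries. Carry-over raises RNAs alike whether or not they persist in heat. Yet among genes whose footprints fell by -4 to -2 on the log2 scale, those that kept their RNA were higher in fust1 than those that lost it by 1.02. A bootstrap over genes, which holds no spread between libraries, gave an SD of 0.116 and a range of 0.778 to 1.23. Simulated carry-over of a 0.1 part of the 22 °C footprints gave -0.0154. This argues against carry-over as the only source for those genes. Below -4, where 26 kept and 15 lost genes left a thin bin, the difference was 0.0809 (-0.315 to 1.02), so there the explanations cannot be told apart. With this bin the whole difference was 0.830. Genes that lost their RNA had a median fust1 minus Col-0 footprint change of 1.21 below -4 (1.29 for kept genes). It was 0.157 from -4 to -3 and -0.272 from -3 to -2. A value that grows with the depth of the fall is what carry-over gives, so a part played by it was not excluded. With footprint libraries thinned to equal totals the TE ratio was 0.683 (0.675 to 0.690), and thinned to equal effective size it was 0.688 (0.680 to 0.696), which argues against depth. Genotype stays open as an untested hypothesis, since a milder heat treatment of the fust1 seedlings was not tested.

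The stress gene RNAs that stood higher in fust1 at 22 °C may reflect a single library or the state of the RNA-seq seedlings. Each of the 9 genes called higher had more counts in both fust1 22 °C libraries than in either Col-0 one. WRKY33, for example, had 1502 and 1704 against 333 and 543. For these genes the higher value does not rest on a single fust1 library. But a call from 2 against 2 libraries favours genes without overlap, so this cannot decide about a single library behind the wider pattern. The defence list median was 0.299 without the fust1 22 °C RNA-seq replicate 1 and 1.37 without replicate 2, where 0.3 or less was set as the sign of a single library, so the margin is narrow. The 8 called genes that footprints could measure had a median footprint change of 0.433 against 2.28 for RNA, and 2 of them were called in footprints. These values met the sign set for an RNA-seq-only state of the seedlings, but the genes were picked by their RNA call, which favours a high RNA value. The 2 footprint calls, ZAT6 (0.67) and ERF2 (0.88), were both higher, against 0.19 expected from the margins, and such a state alone would not give them. STZ (1.74 in RNA and 1.52 in footprints), FRK1 (1.52 and 1.22) and COR15A (1.5 and 1.25), called in footprints alone, had like values in both assays, so such a state stays open. Lower translation of the RNAs called higher stays open as well, because the TE test called none of them at 22 °C, and the same doubt holds for the heat-by-genotype values of ERF-1, WRKY33 and ERF2 in RNA, which include this level.

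The positive RNA median of ribosomal proteins and the negative TE median of cell division and histone genes in heat by genotype could come from a single library or from reads split between copies. Without the Col-0 37 °C RNA-seq replicate 2 the ribosomal protein median was 0.491, and 1.06 without replicate 1, so a library effect and a genotype effect cannot be told apart. Counts summed over 13 H3 and H4 genes still gave a TE change of -1.51 (-2.04 to -0.98), with 0.51 for RNA and -1.0 for footprints. This argues against reads moved between these copies. Reads left uncounted for matching several copies, if any, would be missing from the sum as well, so that cause was not tested.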

How the results depend on the processing

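The thinned libraries and the minimum of 500 footprints were chosen after the results were seen, and the other alternatives were planned. Heat counts of footprints and TE stayed within 1.5 times in every alternative, and heat counts of RNA left that range only when a library was left out (3497 and 3988 in Col-0, 4685 and 4185 in fust1). Genotype and heat-by-genotype counts moved in all assays. The cause was not tested, though the Col-0 37 °C replicates differed most among RNA-seq groups. RLE scaling and nuclear genes only left 15 of 15 counts within 1.5 times and shifted log2 values by at most 0.066 (RLE). DESeq2 moved 6 counts: RNA genotype at 22 °C from 11 to 83, RNA genotype at 37 °C from 10 to 305, RNA heat by genotype from 6 to 178, and for TE from 1 to 18, 235 to 513 and 195 to 667. Without the filter the RNA counts were 57, 195 and 122. Replicate number as a block gave 4, 1 and 0 for RNA and 87 and 63 for TE at 37 °C and heat by genotype, while correlations of replicate residuals between groups ran from -0.291 to 0.227. They were positive for RNA between genotypes at 22 °C (0.175) and 37 °C (0.227) and for fust1 22 °C RNA with footprints (0.195), with both signs in other pairs, so pairing by number was neither shown nor excluded. With only the groups compared, RNA gave 98 and 1, footprints 1949 (22 °C) and 1230 (37 °C) and TE 12 and 2. With DESeq2 49.3 % of the calls for footprints by genotype at 37 °C were higher, against 56.9 %.

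With 1 library left out, where the lone sample is assumed to vary like the other groups, counts ranged for RNA over 3497 to 7292 (heat in Col-0), 4185 to 8433 (heat in fust1), 1 to 67 (22 °C), 1 to 1678 (37 °C) and 0 to 766 (heat by genotype). For footprints they ranged over 9460 to 11427, 9092 to 11312, 141 to 1371, 780 to 2228 and 701 to 1887, and for TE over 5021 to 6871, 3493 to 5742, 0 to 10, 15 to 1276 and 23 to 1445. The ratio of heat responses moved to 0.919 (RNA) and 0.799 (footprints) over genes with at least 100 counts, to 0.882 and 0.785 without the heat lists, to 0.925, 0.846 and 0.706 (TE) with 500 footprints, to 0.812 for footprints thinned to equal totals, and to 0.822 and 0.688 (TE) when thinned to equal effective size. With an estimated correlation 78 of the 93 list calls were lost and 15 kept. Leaving out a library turned camera's direction for 4 lists with a call in the full or the reduced data. Sign changes of list medians without a call were not counted. By median, these lists in RNA at 22 °C were ABA, drought and cold genes (-0.0106, range to 0.606) and cytosolic ribosomal proteins (0.173, range from -0.258), without the fust1 22 °C RNA-seq replicate 1. In TE they were nuclear photosynthesis genes at 22 °C (-0.281, range to 0.249) without the fust1 22 °C RNA-seq replicate 2, and shoot epidermis and stomata markers at 37 °C (-0.73, range to 0.324) without the Col-0 37 °C RNA-seq replicate 1. The relation of TE to transcript features was not run for want of an annotation, and ribosomal RNA genes could not be left out.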

Other observations

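The set of SPL genes and its test were fixed before their genotype values were seen, but SQN itself, its neighbours and the organelle shares were picked after their values were seen. Mitochondrial genes gained RNA share in heat, from 0.00173 ± 0.000418 % to 0.0531 ± 0.00943 % in Col-0 and from 0.00156 ± 0.000483 % to 0.0589 ± 0.00197 % in fust1 (mean ± SD, n = 2), though poly(A) selection holds few of them. Their footprint share was 0.0144 ± 0.00323 % and 0.00939 ± 0.00314 % in Col-0 and 0.0168 ± 0.00192 % and 0.00733 ± 0.00127 % in fust1. The 10 most counted genes held 36.4 % of Col-0 footprints at 37 °C and 34.7 % of fust1 footprints, against 8.76 % and 7.85 % at 22 °C.

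At unadjusted p < 0.05, SQN alone was at least 4-fold lower in fust1 at both temperatures in both assays. By that rule 5 genes (AT1G15540, AT1G68040, LAS1, CYP76G1 and MAF5) were higher, but none of them was called in RNA at either temperature. In Col-0, SQN RNA rose in heat (3.38 ± 0.24, adjusted p = 3.22e-06). SQN footprints rose less (1.16 ± 0.32, adjusted p = 0.0031), and its TE fell (-2.22 ± 0.43, adjusted p = 8e-04). The tested neighbours of SQN, both at higher locus numbers, were not called for RNA in fust1 at 22 °C: OTP51 had -0.24 ± 0.25, adjusted p = 1.0 and AT2G15830 had 0.59 ± 0.64, adjusted p = 1.0. The nearest genes at lower locus numbers gave no test result, so a loss reaching that way was not addressed.

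SQN is known to help microRNAs act, and its loss lowers miR156 activity, so its absence could raise SPL RNAs in fust1. The median RNA change of 9 SPL genes at 22 °C was 0.46 (-0.06 to 1.36), and camera called the set with its preset correlation, as lower miR156 activity would give. The call was lost with an estimated correlation, and edgeR called 0 of the 9 (SPL3 1.36, adjusted p = 0.312), so the hypothesis stays weak. Whether SQN loss is part of the fust1 line or a second lesion was not tested, and some differences of the mutant may belong to SQN.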
